A study of Apis mellifera with 12 samples.

How the data were processed

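The samples were 12 pools of small RNA from honey bee fat body, 6 from workers injected with dsRNA against vitellogenin (dsRNA-Vg) and 6 from workers injected with dsRNA against GFP (dsRNA-GFP, the sham control). Per the labels' protocols, newly emerged workers received 2 µL of dsRNA at 10 µg/µL, bees were 15 days old when sampled, and each of 5 bees gave 400 ng to a pool of 2 µg of RNA. The series' design text calls the pools biological samples made of different bees, and the labels describe foragers. Per the labels' protocols, small RNA was extended at its 3' end with a poly(A) tail, ligated to a tag and stained with Cy3 by a service provider (LC Sciences), so each array has 1 colour. Per the file headers, each deposited scanner file holds the median intensity of every spot of 1 array, with no column of local background. An array had 3968 spots: 168 bee miRNA reporters in 18 spots each, 628 empty spots and 316 other control spots. A deposited value table holds 1 intensity per miRNA and pool. Its values are whole numbers on a linear scale from 4 to 44058 with medians of 24.0 to 41.5 per array, and the way the authors corrected and normalized these intensities is not given in the sources used here. Its Spearman correlation with the scanner values was 0.896 to 0.983 over the 12 arrays. Its scale was read from the slope of its log2 values on those of the scanner less a surface of the empty spots, over the 35 probes detected on all arrays, which was 0.80 to 1.12 per array, where a linear scale gives about 1. Both are across miRNAs, which are not independent replicates. Its centring between arrays stays unknown.

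Scanner intensities were corrected with limma's normexp method (limma 3.58.1 in R 4.3.3, offset 50) fitted on all spots of an array, since no local background was given. The design written before the data were examined had assumed a local background, and the global form was taken once the columns were known and before any comparison of the groups. Control spots were then left out, log2 values of the miRNA spots were quantile normalized between arrays, and the 18 spots of a probe were averaged. The offset shrinks the fold changes of dim probes, and quantile normalization holds the brightest probes near fixed values. A probe counted as detected on an array when at least 50% of its spots exceeded the 95th percentile of that array's empty spots, which ranged from 164.4 to 544.8. Probes detected on at least 6 of 12 arrays were tested, which kept 127 and left out 41, and 35 were detected on all 12. On 2 arrays the median of the dimmer probes lay under that of the empty spots, so detection against empty spots is strict there. On dsRNA-GFP pools 1, 2, 3 and 6 and dsRNA-Vg pool 3 the median of the dimmer probes lay above that 95th percentile. Detection is lenient there, with 139 to 168 probes detected per array. With detection set against the dimmer miRNA probes, 61 probes were tested, so many of the 127 lie near the background. The highest spot read 61540, under the limit of 65535 of a 16-bit scan. Within an array, the 18 spots of a probe had a median coefficient of variation of 6.66% to 15.4% over the probes detected on all arrays, and the number of arrays limits the precision. Correlations between arrays over tested probes were 0.921 to 0.996, and 0 pairs of arrays held identical values.

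The groups were compared with limma (lmFit and eBayes on log2 intensity, group only), with Benjamini-Hochberg adjustment over the 127 probes and a threshold of 0.05. Lists of miRNAs were fixed before the data were examined, 16 in all, and the 12 with 3 or more tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry. Lists with fewer members are given as single values. The number of detected probes and the median signal per array were compared with two-sided exact permutation tests, whose smallest possible p is 0.00216. The miRNAs named were those past the threshold (2), the next by p until 20 were named, the 5 with the highest mean intensity, and members of the fixed lists, matched by name without the species prefix or arm. Of the 168 probes, 149 had a miRNA gene of the same name in the RefSeq table of assembly Amel_HAv3.1. The files name no genome build, so no coordinates are given. Relations of the control reporters with the miRNAs were tested with 100000 permutations within the groups. Sequence likeness was counted as the most matching positions of 2 mature sequences over all alignments without gaps.

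The fit was tested on simulated data made for this comparison from 127 probes, with 30 changed in each of 50 simulations. It recovered 84.1% of changes of 0.5 on the log2 scale, 95.1% of changes of 1 and 98.9% of changes of 2, with 3.30% to 3.58% of calls false. Changes were added after normalization to independent noise with each probe's own SD, so shrinkage by the offset is left out. With 30 changed probes the adjustment is also easier to pass than with few. The shares are averages over probes, many with a small SD near the background. They need not hold for widely varying probes such as miR-750 (SD 1.98 after dsRNA-GFP). Alternatives were cyclic loess, median scaling and no normalization between arrays, no background correction, subtraction of a loess surface of the empty spots in place of a local background (values under 1 set to 1), other filters, a trended robust prior, array weights, the pool number as a block, the deposited value table, and leaving out each pool in turn. Alternatives added after the data were seen were normexp with the empty spots as negative controls, detection against the dimmer miRNA probes (above their median by 3 times the median absolute deviation), and 3 covariates: the mean of miR-750 and miR-1175, and the control reporters PUC2PM and a-PUC2PM. Whether the groups could arise by chance was checked on 100 of the 462 splits of the arrays into 6 and 6, drawn with a fixed seed. Figures were drawn with matplotlib. No slide, scan day or other batch was analysed here, and the sequences of the injected dsRNA were not used here.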

Results

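MicroRNA (miRNA) levels were measured in the fat body of honey bee workers (Apis mellifera), the insect tissue that stores nutrients and makes yolk protein. Newly emerged workers had been injected with double-stranded RNA (dsRNA) against vitellogenin, a yolk precursor protein that also circulates in sterile workers, or with dsRNA against green fluorescent protein (GFP), which served as the sham control. No uninjected bees were among the samples, so each difference is between dsRNA-Vg and dsRNA-GFP. Fat body lining the abdominal carcass was taken from adults 15 days old. Each group held 6 pools of 5 bees, and each pool was hybridised to 1 array, which gives 12 arrays. The array carried 168 bee miRNA probes in 18 spots each, and a probe is named here by its miRNA. Empty spots had median intensities of 150.2 to 491.3 over the 12 arrays, and 37 to 168 miRNA probes per array were detected above them. After dsRNA-Vg, 96.3 ± 46.6 probes were detected per array (SD, n = 6), and after dsRNA-GFP 114.8 ± 57.4 (SD, n = 6), a difference of -18.5 that lay within the spread between pools (two-sided exact permutation p = 0.539). The difference rests on single pools: it was -7.87 without dsRNA-GFP pool 1, -10.5 without dsRNA-GFP pool 2, and -10.8 and -8.03 without dsRNA-Vg pools 2 and 6, but -34.1 and -32.1 without dsRNA-GFP pools 4 and 5 and -31.8 without dsRNA-Vg pool 3. With detection set against the dimmer miRNA probes it was 0.83, and with a subtracted background surface -29.2 (exact permutation p = 0.522). The log2 median signal before normalization between arrays was 6.85 ± 0.29 after dsRNA-Vg and 7.10 ± 0.41 after dsRNA-GFP (SD, n = 6 each), which did not differ by more than the pools did (difference -0.25, two-sided exact permutation p = 0.26), and without dsRNA-GFP pool 1 the difference was -0.13. With a subtracted background surface it was -0.94 (exact permutation p = 0.444). No probe for the vitellogenin mRNA was used here, so the knockdown itself was not analysed here.

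A few probes gave most of the summed array signal. Probes differ in how well they hybridise, so these shares describe the signal and are not abundances of the miRNAs. In the deposited value table, miR-8, which acts in insulin and steroid signalling in the fly fat body, took 24.2% ± 2.13 of the summed intensity (SD over 12 pools). miR-276 took 17.1% ± 3.41 and miR-2 took 9.17% ± 1.10, and these 3 miRNAs together took 50.5%. With miR-307 at 6.74% and miR-317 at 5.46%, they were the 5 probes with the highest mean log2 intensity. None of these 5 passed the threshold for a difference between the groups, with log2 fold changes of -0.01 for miR-8 (SE 0.14) and 0.01 for miR-276 (SE 0.14), although quantile normalization holds the brightest probes of an array near fixed values.

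The comparison of dsRNA-Vg with dsRNA-GFP asks which fat body miRNAs differ when vitellogenin is targeted by RNA interference. Of 127 miRNAs tested, 2 rose after dsRNA-Vg and 0 fell. miR-3739 was 5.71-fold higher (95% CI 3.25 to 10.0), at a log2 intensity of 10.80 ± 0.59 after dsRNA-Vg and 8.29 ± 0.78 after dsRNA-GFP (SD, n = 6 each). miR-3776 was 2.34-fold higher (95% CI 1.67 to 3.27), at 8.36 ± 0.51 against 7.14 ± 0.27 (SD, n = 6 each). For both miRNAs, each of the 6 dsRNA-Vg pools lay above every dsRNA-GFP pool, which chance gives a single miRNA, in either direction, in a share of 0.00216 of arrangements. Both were picked by p from 127 on these same values, so this share is not separate evidence. miR-13a, which was not called (limma adjusted p = 0.155), was also separated, with all 6 dsRNA-Vg pools below every dsRNA-GFP pool. For miR-3776 the nearest pools were 0.02 apart, which is within the standard errors over their spots (0.044 and 0.052), so their order is not resolved. No function is assigned to either miRNA here.

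**Figure D1:**
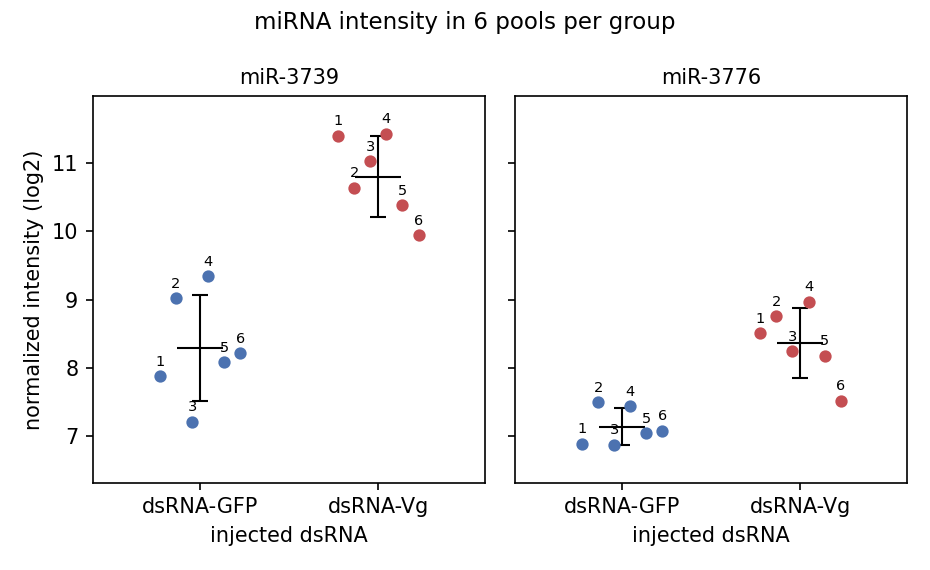
Normalized log2 intensity (vertical axis) of miR-3739 and miR-3776 in each of the 6 dsRNA-GFP pools (blue) and 6 dsRNA-Vg pools (red), with pool numbers beside the points, the group mean as a bar and the SD as whiskers. The lowest dsRNA-Vg pool lies above the highest dsRNA-GFP pool for miR-3739 (9.94 against 9.34), and for miR-3776 these pools nearly meet (7.52 against 7.50).

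By limma, the log2 fold change was 2.51 for miR-3739 (SE 0.37, adjusted p = 0.00305) and 1.23 for miR-3776 (SE 0.22, adjusted p = 0.00909). miR-3739 was detected on all 12 arrays. miR-3776 was detected on 4 of the 6 dsRNA-GFP arrays and on all 6 dsRNA-Vg arrays, so its fold change depends on how background is treated. Its log2 fold change was 0.665 without background correction and 2.96 with a subtracted background surface. In the deposited value table miR-3739 had an intensity of 2885 ± 1006 after dsRNA-Vg and 370.5 ± 301.7 after dsRNA-GFP (SD, n = 6 each), a 10.1-fold difference by limma (95% CI 4.73 to 21.6, adjusted p = 0.00189). In that table miR-3776 had an intensity of 373.0 ± 243.3 against 63.8 ± 39.1 (SD, n = 6 each), a 5.78-fold difference (95% CI 2.78 to 12, limma adjusted p = 0.0101). The mature sequences are alike: UUGGGAGGGGGAGAGAGCAGCU for miR-3739 and AGGAGGGGGGGAGAGAGAAGCG for miR-3776 share 16 matching positions without gaps and a longest common run of 11 bases. miR-3741 (ACGAGAGGGGGAGAGAGAAGUA), which matches miR-3739 at 16 positions with a common run of 13 bases and was chosen after its values were seen, had a log2 fold change of 0.08 (SE 0.09, limma adjusted p = 0.686), but lay near the background, with detection on 3 of 6 dsRNA-GFP and 4 of 6 dsRNA-Vg arrays. The control reporter PUC2PM, a calibration spike per the scanner files whose added amounts are not given in the sources used here, also had a brighter signal on the dsRNA-Vg arrays, at 11.18 ± 0.74 against 9.77 ± 0.62 on the log2 scale before normalization between arrays (SD, n = 6 each, limma adjusted p = 0.0412). With PUC2PM as a covariate, miR-3739 had a log2 fold change of 1.95 (SE 0.54, limma adjusted p = 0.143) and miR-3776 one of 0.72 (SE 0.28, limma adjusted p = 0.417), and 0 miRNAs passed the threshold. PUC2PM was taken as a covariate after its difference between the groups was seen. Such a covariate takes up part of any group difference and widens the errors, so this fit alone cannot decide whether the calls come from labelling or hybridization. The call of miR-3776 also ended with scaling to the median (log2 fold change 0.81, limma adjusted p = 0.525) and without normalization between arrays (0.99, limma adjusted p = 0.256), where the median of all miRNAs itself lay at -0.41 and -0.22.

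None of the other 125 miRNAs passed the threshold, and the next 18 by p are given as values and not as calls. Among all 127 tested, at an unadjusted p under 0.05, 12 miRNAs had a positive and 6 a negative log2 fold change. Chance would give 6.35 in all. These counts include the 2 called miRNAs. The next 18 by p leave those 2 out and extend past that bound to miR-3727 and miR-3789. The largest positive values among the 18 were 0.47 for miR-263b (SE 0.15) and 0.44 for miR-133 (SE 0.17), and miR-13b and miR-34 each had 0.33. The largest negative values were -0.90 for miR-3789 (SE 0.42), -0.46 for miR-281 (SE 0.20) and -0.31 for miR-14 (SE 0.12). miR-3788, miR-13b and miR-3796 had the smallest limma adjusted p among them, 0.145 each.

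**Figure D2:**
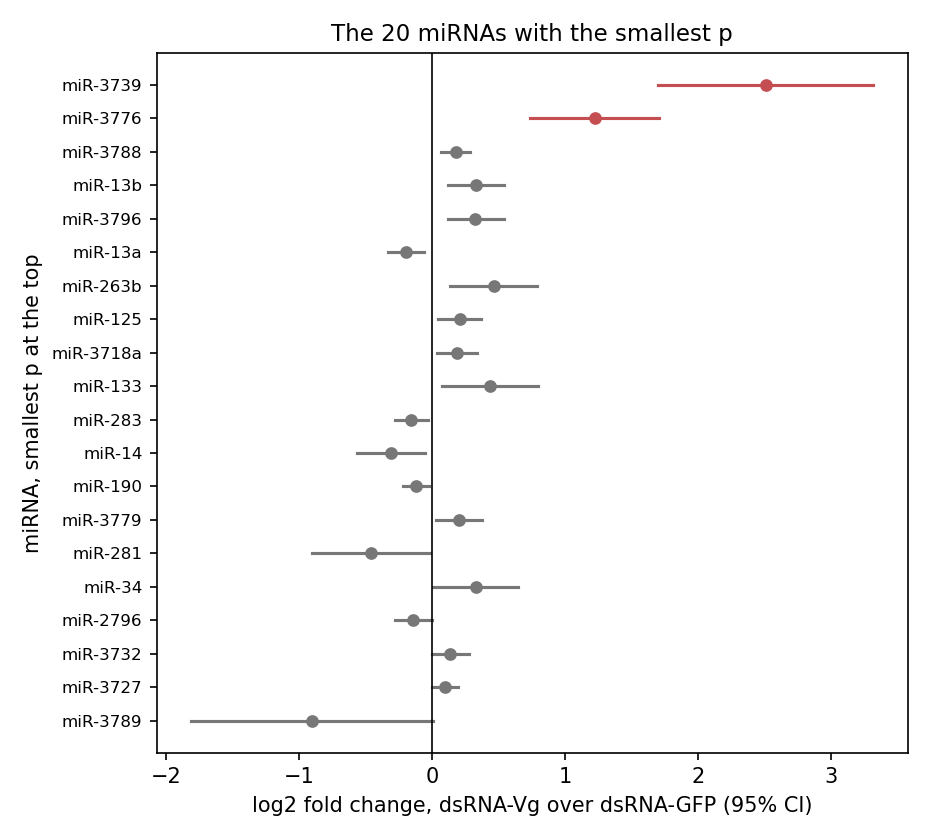
Log2 fold change of dsRNA-Vg over dsRNA-GFP (horizontal axis, lines are 95% confidence intervals) for the 20 miRNAs with the smallest p, in that order from the top, with the 2 past the threshold in red and the rest in grey. The intervals of miR-3739 (1.70 to 3.32) and miR-3776 (0.74 to 1.71) lie farther above 0 than those of the other 18.

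Among miRNAs of fat body metabolism and insulin signalling, 0 of 7 tested members passed the threshold. miR-14, which limits fat storage in the fly, had a log2 fold change of -0.31 (SE 0.12), miR-278, which bears on insulin sensitivity in the fly, 0.41 (SE 0.29), and miR-277, which acts on branched-chain amino acid breakdown in the fly, 0.03 (SE 0.20). By camera the list did not shift against the other miRNAs (adjusted p = 0.852), with a mean of 0.02 and a median of -0.01. Of the miRNAs regulated around vitellogenesis in female mosquitoes, 0 of 6 tested members passed the threshold, and the values ran from -0.01 for miR-8 to 0.14 for miR-275, which is needed for egg development in mosquitoes. This list had an unadjusted p of 0.0147 by fry, the test of whether members move one way on balance, which did not pass after adjustment over the lists (adjusted p = 0.124, camera adjusted p = 0.852).

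In the main fit no cluster passed camera, which sets the mean shift of a list against the other miRNAs. Camera does not test whether the members vary together. In the cluster of miR-71, miR-2, miR-13a and miR-13b, 0 of 4 members passed over all miRNAs tested, and adjusted over the list alone 1 rose and 1 fell: miR-13b (log2 fold change 0.33, SE 0.10) and miR-13a (-0.20, SE 0.06), both at a limma adjusted p of 0.0161. miR-13b did not pass this test with cyclic loess (0.20, adjusted p = 0.231), and neither passed with scaling to the median, without normalization between arrays, with the replicate block or in the deposited table. miR-13b passed in 19 of 28 alternatives and miR-13a in 12 of 20. miR-13a was detected on only 2 dsRNA-Vg and 4 dsRNA-GFP arrays. In the let-7 complex, a set of miRNAs tied to developmental timing, 0 of 3 members passed over all miRNAs tested. Adjusted over the list alone, 1 rose: miR-125 (0.21, SE 0.07, limma adjusted p = 0.044), which did not pass with cyclic loess (adjusted p = 0.214) and whose value was negative with scaling to the median (-0.22) and without normalization between arrays (-0.03). It passed in 10 of 28 alternatives, and not without dsRNA-GFP pool 2, 5 or 6 or dsRNA-Vg pool 1, 2, 3 or 4 (adjusted p 0.0888 to 0.141). let-7 had -0.33 (SE 0.20), and the list's mean was -0.01 with a median of 0.08 and an upward camera direction (adjusted p = 0.852). The 3 members of the cluster of miR-12, miR-283 and miR-3477 had negative values with a mean of -0.21 (camera adjusted p = 0.68, fry unadjusted p = 0.0207 and adjusted p = 0.124). The cluster of miR-9a, miR-79 and miR-306 (4 tested), that of miR-277, miR-317 and miR-34 (3), the seed family of miR-279 and miR-996 (4), the Hox cluster with the miR-10 family (3) and the miR-92 seed family (2) had 0 calls, also adjusted over the list alone. Of 61 miRNAs numbered 3000 or above, 2 rose and 59 did not pass, adjusted over the list alone as well, with a camera adjusted p of 0.852. Fry's test of change in either direction passed for this list alone among the 12 tested (adjusted p = 0.0149), and both called miRNAs are members of it. With an estimated correlation, 0 of 12 lists passed camera, as with the preset one.

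Markers of other tissues were measured because a carcass also holds muscle, nerve and epidermis. Of the muscle miRNAs, miR-1 had a log2 fold change of -0.44 (SE 0.32, limma adjusted p = 0.535) and miR-133 one of 0.44 (SE 0.17, limma adjusted p = 0.217). miR-1 read 9.62 in dsRNA-GFP pool 3 against 11.15 to 11.43 in the other dsRNA-GFP pools, so that pool draws its value towards 0. Adjusted over the list alone, miR-133 rose (limma adjusted p = 0.043), but not with cyclic loess (0.20, adjusted p = 0.0601), scaling to the median (0.01, adjusted p = 0.965) or no normalization between arrays (0.20, adjusted p = 0.451). It passed in 12 of 28 alternatives: the replicate block (adjusted p = 0.0884), the deposited table (adjusted p = 0.0744) and the removal of dsRNA-GFP pool 1 or 2 or any dsRNA-Vg pool (adjusted p 0.0506 to 0.102) also ended it. Among the 4 sensory and epithelial markers, miR-263b rose adjusted over the list alone (limma adjusted p = 0.0342), and 0 passed over all miRNAs tested. This call too was absent with cyclic loess (0.24, adjusted p = 0.17), scaling to the median (0.09, adjusted p = 0.85) and no normalization between arrays (0.28, adjusted p = 0.531). It passed in 10 of 28 alternatives: the replicate block (adjusted p = 0.0677), the deposited table (adjusted p = 0.849) and the removal of dsRNA-GFP pool 1, 2, 3 or 4 or dsRNA-Vg pool 2, 3, 5 or 6 (adjusted p 0.0516 to 0.092) also ended it. Of the 6 nervous system markers tested and the 2 ovary markers tested, 0 passed in either way, and all 8 had log2 fold changes between -0.11 and 0.09. Their group means were 6.93 to 7.51, near the background, where the offset shrinks changes. In the deposited table they ran from -0.52 for miR-7 (limma adjusted p = 0.227) to 0.37 for miR-989 (limma adjusted p = 0.44). The narrow range thus does not show that these tissues were equal. The midgut markers miR-1175 and miR-281 had log2 fold changes of -1.17 (SE 0.68, limma adjusted p = 0.42) and -0.46 (SE 0.20, limma adjusted p = 0.33), and 0 passed in either way. miR-1175 was bright in single pools: it had a log2 intensity of at least 8.84 in dsRNA-GFP pools 1, 2, 3 and 5 and in dsRNA-Vg pool 3, and of at most 7.46 in the other 7 pools. miR-750, whose gene lies next to that of miR-1175 in the Amel_HAv3.1 assembly with 0 genes between them, was chosen after its values were seen. It was at 10.76 or above in those same 5 pools and at 7.72 or below in the other 7 (log2 fold change -1.89, SE 0.99, limma adjusted p = 0.375). With the mean of miR-750 and miR-1175 as a covariate, the log2 fold changes of miR-3739 and miR-3776 were 2.33 (limma adjusted p = 0.0238) and 1.14 (limma adjusted p = 0.0605).

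**Figure D3:**
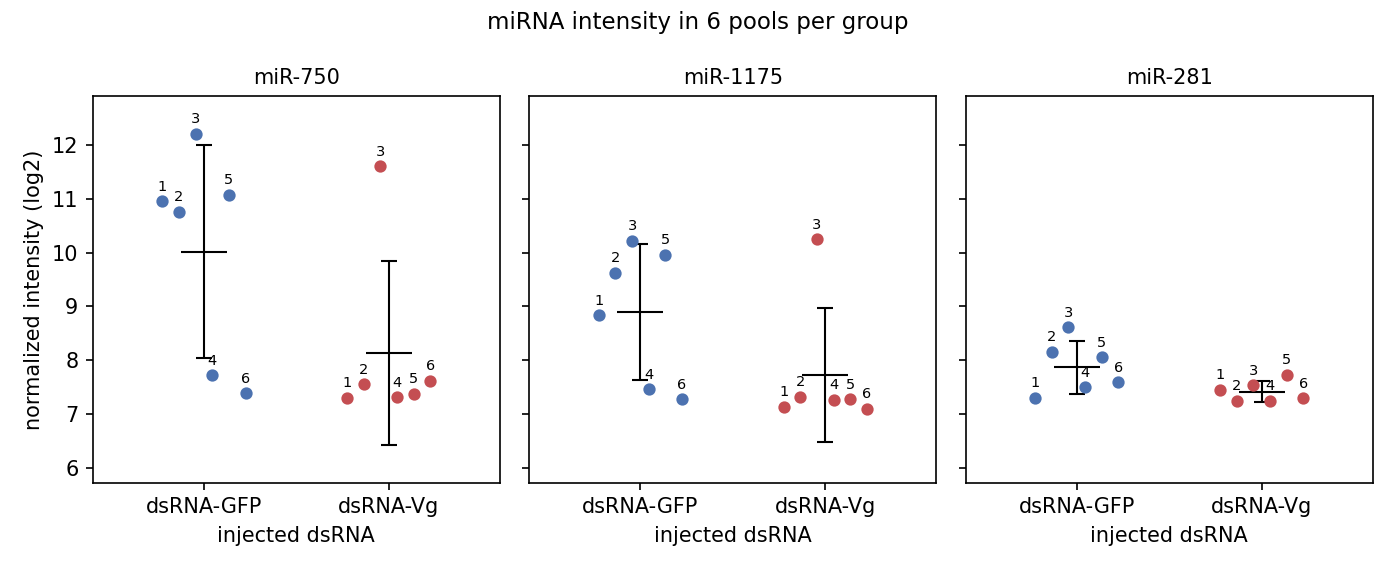
Normalized log2 intensity (vertical axis) of miR-750, miR-1175 and miR-281 in each of the 6 dsRNA-GFP pools (blue) and 6 dsRNA-Vg pools (red), with pool numbers beside the points, the group mean as a bar and the SD as whiskers. miR-750 and miR-1175 are bright in dsRNA-GFP pools 1, 2, 3 and 5 and in dsRNA-Vg pool 3, while miR-281 ranges from 7.25 to 8.62 with dsRNA-GFP pool 3 at the top.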

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

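Of the tests in this part, the correlations, the control reporter covariate, normexp with the empty spots as negative controls, the bounds that judge the settings compared for each miRNA and every test on miR-750 and miR-1175 were chosen after the result was seen, and the count of splits and the other settings were planned.

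Single pools stood far from the other 5 of their group in 6 of the 50 groups of 6 values checked, where chance gives about 2.5. miR-3788 read 7.13 in dsRNA-GFP pool 1 against at most 7.04 in the others, and miR-3732 read 7.22 in dsRNA-GFP pool 6 against at most 7.03. miR-3727 read 6.85 in dsRNA-GFP pool 5 against at least 6.94. miR-2 read 13.69 in dsRNA-GFP pool 1, where the other 5 all read 13.78, a value that quantile normalization fixes for a probe of constant rank. miR-317 read 13.26 in dsRNA-GFP pool 3 against at most 13.07, and 12.96 in dsRNA-Vg pool 4 against at least 13.04.

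The calibration control reporters, which the comparison of miRNAs does not use, gave a signal that differed between the groups. Before normalization between arrays, PUC2PM was higher by 1.41 on the log2 scale after dsRNA-Vg (9.77 ± 0.62 to 11.18 ± 0.74, SD, n = 6 each, limma adjusted p = 0.0412), with 4 of 6 dsRNA-Vg arrays above every dsRNA-GFP array. a-PUC2PM was higher by 1.37 (limma adjusted p = 0.0383), with 5 of 6 arrays above. These were 2 of 55 control reporters past the threshold, 4 had an unadjusted p under 0.05, and the reporter PUC2PM-20B differed by -0.12 (SE 0.40).

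For the brighter miR-3739 and miR-3776 after dsRNA-Vg, normalization and background treatment are argued against for miR-3739, which passed the threshold in 7 of 7 other settings with a lowest log2 fold change of 1.93, but not for miR-3776, whose adjusted p reached 0.525 while its distance from the median of all miRNAs stayed at 1.22 in that setting. Labelling or hybridization that differed between the groups stays open: with PUC2PM as a covariate the log2 fold change of miR-3739 went from 2.51 (SE 0.37) to 1.95 (SE 0.54), and the call ended because the fold shrank and the error grew, as the covariate itself differs between the groups. What that means depends on whether the spike was added in equal amounts, which is not given in the sources used here, and over 12 arrays its deviations from the group means were not clearly related to those of miR-3739 (r = 0.39, permutation p = 0.219, rho 0.51, p = 0.101; r = 0.76 without the 2 farthest arrays) or miR-3776 (r = 0.59, permutation p = 0.0634, rho 0.63, p = 0.0466; r = 0.69), with adjusted p over 4 relations of 0.187 or more. A single RNA captured by both probes also stays open: the probes correlated over 6 pools at r = 0.95 in dsRNA-GFP (exact permutation p = 0.00556, adjusted over both groups 0.0111, rho 0.94, p = 0.0167) and r = 0.78 in dsRNA-Vg (exact permutation p = 0.0514, adjusted 0.0514, rho 0.83, p = 0.0583), and without the 2 pools farthest from the median they were 1.00 in dsRNA-GFP and 0.15 in dsRNA-Vg, so the latter rests on those pools. An effect of less vitellogenin, and pieces of the injected dsRNA read by these probes, may each give the pattern too, and both are confounded with the groups and untested.

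The second pattern is the count of 2 changed miRNAs itself. Of 100 splits of the 12 arrays drawn, 5 gave at least 2 calls, the real one included, and the highest other split gave 4, so chance cannot be excluded by the count.

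The third pattern is the bright miR-750 and miR-1175 on 5 arrays, 4 of dsRNA-GFP and 1 of dsRNA-Vg. Normalization is argued against, since the same 5 arrays were the brightest for both miRNAs in 8 of 8 settings, the deposited table and unnormalized values among them. A swap of dsRNA-Vg pool 3 with a dsRNA-GFP pool is argued against: miR-3739 was still called without that pool and each dsRNA-GFP pool in turn (log2 fold change 2.35 to 2.71, limma adjusted p at most 0.0321), and it read 11.03 there, within the other dsRNA-Vg pools (9.94 to 11.43) and 1.69 above the highest dsRNA-GFP array (SD 0.78, n = 6). Midgut tissue carried over in dissection may be a source, and it cannot be told apart from a change within the fat body: miR-281, the other midgut marker of the fixed list that was measured, was above the other 7 arrays on 3 of the 5 (dsRNA-GFP pools 2, 3 and 5) and within their range on dsRNA-GFP pool 1 (7.30) and dsRNA-Vg pool 3 (7.54). The comparison of the groups called neither miRNA (limma adjusted p = 0.375 for miR-750 and 0.42 for miR-1175), and 1 dsRNA-Vg pool shows the pattern. An effect of the knockdown on them is thus neither shown nor excluded.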

How the results depend on the processing

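Detection against the dimmer probes, empty spots as negative controls and the 3 covariates were chosen after the data were seen, and the other settings before. miR-3739 kept its direction in every setting and its call in all but the control reporter covariates, which gave 1.95 (SE 0.54, limma adjusted p = 0.143) with PUC2PM and 2.00 (SE 0.60, limma adjusted p = 0.32) with a-PUC2PM. miR-3776 kept its direction wherever it was tested and lost its call with PUC2PM (0.72), a-PUC2PM (0.82), the mean of miR-750 and miR-1175 (1.14), median scaling (0.81) and no normalization (0.99). Median scaling and no normalization moved the median of all miRNAs by -0.41 and -0.22, and relative to it miR-3776 stood at 1.22 in both. Over all alternatives the adjusted p ran from 0.000167 to 0.32 for miR-3739 and from 0.000774 to 0.525 for miR-3776. The count of higher miRNAs was thus 1 in these last 3 settings and among the 35 probes detected on all arrays, where miR-3776 was not tested, and 0 with either control reporter. It was 3 with a subtracted background surface (adding miR-3788) and without dsRNA-GFP replicate 5 (adding miR-263b), and 2 without any other pool, where miR-3739 ran from 2.37 to 2.72 and miR-3776 from 1.07 to 1.41. The count of lower miRNAs was 0 in every setting run by limma, with 6 at an unadjusted p under 0.05. With the pool number as a replicate block, 3 miRNAs were higher (adding miR-3796). Whether the numbers pair the pools is not known. Same-numbered pools correlated at -0.33 to 0.70, 3 of 6 above 0.1, and 2 of 6 dsRNA-GFP pools correlated best with their own number. Such correlations cannot exclude a shared batch. The block lowered the SE of miR-3739 from 0.371 to 0.333 and that of miR-3776 from 0.22 to 0.153. Without normalization 2 lists passed camera (the cluster of miR-277, miR-317 and miR-34 and the mosquito list, adjusted p = 0.0297 each), against 0 in all other settings. The difference in detected probes was 0.83 by detection against the dimmer probes and -29.2 with a subtracted background surface, against -18.5 (-34.1 to -7.87 without 1 pool), and that in median signal was -0.94 with this surface against -0.25, with none past its exact permutation test. Except where a covariate or fewer tested probes enter, the cause was not tested. miR-3776 counted as detected on 4 of 6 dsRNA-GFP arrays, a rule that depends on the empty spots of each array. It read 6.89 and 6.87 on dsRNA-GFP pools 1 and 3, where it was detected, and 7.44 on pool 4, where it was not. Its dsRNA-GFP values thus lie near the background, which limits its fold change. A slide or scan batch was not run because no batch was analysed here.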

Other observations

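The tests of sequence likeness in this part were chosen after the values of some of these miRNAs had been seen.

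The variation between the pools was led by a pair of neighbouring miRNAs. The first principal component of the 127 miRNAs took 54.8% of the variance, with miR-750 giving 47.7% and miR-1175 19.5% of its squared loadings, and miR-3739 11.9%. In the deposited table, miR-750 ranged from 61 in dsRNA-Vg pool 1 to 5040 in dsRNA-GFP pool 3, and miR-1175 from 47 in dsRNA-Vg pool 6 to 1507 in dsRNA-GFP pool 5. miR-3789 varied widely within dsRNA-GFP (8.45 ± 1.00, SD, n = 6) and less within dsRNA-Vg (7.55 ± 0.43, SD, n = 6), a difference in spread that was not tested.

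A hypothesis was that probes gain signal after dsRNA-Vg because of purine-rich sequence shared with miR-3739. Across the 125 other tested miRNAs without miR-3776, matching positions with miR-3739 and log2 fold change were not related (Spearman rho -0.06, permutation p = 0.537, adjusted over 4 relations 0.859, across miRNAs, which are not independent replicates). The share of purines had a rho of -0.20 (permutation p = 0.0264, adjusted p = 0.106), the opposite direction. miR-3741, which shares a longer run with miR-3739 than miR-3776 does, had a log2 fold change of 0.08 (SE 0.09), and of 0.48 (SE 0.43) in the deposited table. It is the only other tested miRNA that matches miR-3739 at 16 or more positions, was detected on 3 dsRNA-GFP and 4 dsRNA-Vg arrays, and decides nothing alone. Among the dsRNA-GFP pools miR-3741 read highest on pools 4 and 2 (7.12 and 7.06), as miR-3739 did (9.34 and 9.02). Among the dsRNA-Vg pools both read highest on pool 4 (7.36 and 11.43), but miR-3741 was lowest on pool 3 (6.79), where miR-3739 read 11.03. Its values lie near the background, and its relation with miR-3739 from pool to pool was not tested. miR-3796, next in likeness at 13 positions, had 0.33 (SE 0.10), and 1.07 in the deposited table (SE 0.285, limma adjusted p = 0.0917). At 12 positions, miR-3717, miR-210 and miR-263b had -0.14, 0.125 and 0.47. The rank correlation runs mostly over unlike miRNAs and says little of the closest ones, so the hypothesis stays open. The 18 spots of miR-3739 and the 18 of miR-3776 were all brighter after dsRNA-Vg on average, by 2.22 to 2.56 and by 0.78 to 1.39 on the log2 scale before normalization between arrays. The spots are copies of a probe on the same arrays, and both probes were picked for this difference, so this is not separate evidence.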
